A study of Homo sapiens with 9 samples.

How the data were processed

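Dissociated skin cells of 4 lesional, 3 perilesional and 2 healthy samples were sequenced as 9 droplet libraries with the 10x Single Cell 3' v2 kit, per the labels' protocols. The labels also describe hashtag antibodies and pooling of donors, but the deposited matrices hold no hashtag features, so a library was the unit of replication. The deposited values are raw UMI counts per gene and cell barcode, which the authors made with bcl2fastq and Cell Ranger on hg19, per the submitters' processing notes. The other deposited files hold text only, the cell barcodes, and the gene identifiers with their symbols. Each library lists 32738 genes, with the same identifiers and symbols in all 9. The headers of the 5 newer-format matrices name software version 3.0.0, and the 4 older-format matrices name none. Barcodes had already been limited to called cells by the authors. Immunoglobulin and T cell receptor constant genes, PECAM1, TPSB2 and GLYCAM1 are not in the deposited gene list, so an immunoglobulin list fixed beforehand was not tested.

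Gene names were taken from the deposited files, and no coordinates are given because the available reference is of another build. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. The share of barcodes over the mitochondrial limit ran from 0.0641% in perilesional replicate 1 to 24.6% in perilesional replicate 3 and 35.9% in lesional replicate 4. Doublets were removed per library with Scrublet's method at an expected rate of 0.06. Where its own threshold marked under 0.5% of cells, as in the 4 older-format libraries, a score of 0.25 was used, and 0.177% to 2.27% of cells were removed. Of 38521 barcodes, 32643 remained. XIST, TSIX, Y-linked genes and V, D and J segments, 110 in all, were left out, which kept 32628 genes. Pairs of libraries shared at most 1.33% of barcodes, and no library was found deposited again under another name.

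Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 40 clusters. A cluster was named for the marker list with the largest share of its genes raised, requiring at least 3 markers at 3-fold over the median of the clusters (10 CPM added to both) in at least 10% of its cells. Clusters with a share of raised markers under 33.3%, with a tie, or with more markers of another class among their 10 leading genes stayed unnamed. The marker lists were chosen beforehand, whereas this scoring rule was set once the clusters had been seen and changed 2 times. Shares of 13 classes, the unnamed one included, were compared as log2 odds (0.5 added to both counts) by a two-sided exact permutation test over libraries, with Benjamini-Hochberg adjustment over the classes. Intervals for single libraries are exact Clopper-Pearson at 95%, and a count of 0 is given the upper limit of 3 counts.

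Counts were summed per library and class where a library held at least 20 cells of the class, and a class was tested where each group kept 2 libraries. Low counts were filtered with filterByExpr, libraries were scaled by TMM, and edgeR's quasi-likelihood test (robust) compared the 3 groups in 1 fit of all libraries, with Benjamini-Hochberg adjustment at 0.05 within each class and comparison. Standard errors of log2 fold changes come from these fits, and CPM values are TMM-scaled unless stated. Site was tested with group as a term beside it. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the lists of a class and comparison. The fry p-value asks whether a list's genes move, on balance, in 1 direction, and does not compare the list with other genes. B cells were not tested for genes, because too few libraries outside lesional skin held 20. Scripts were tested on counts simulated from the real means and library sizes. For lesional against perilesional keratinocytes, 90% of genes changed 8-fold and 36% of those changed 4-fold were recovered. For lesional against healthy skin, it was 78% of pericyte and 46% of macrophage or dendritic genes changed 8-fold. Real power may be lower, so a count of 0 does not exclude changes.

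For each class and comparison, the named genes were the 5 with the largest log2 fold change in each direction among genes past an adjusted p of 0.05, with values that did not overlap between the groups and a mean of at least 10 CPM. Left out were mitochondrial and ribosomal protein genes, XIST, TSIX and Y-linked genes, V, D and J segments, HLA-DRB3, HLA-DRB4, HLA-DRB5, GSTM1, GSTT1, UGT2B17, clone names and markers of another class. For each gene list, up to 4 members past 0.05 with the smallest adjusted p were named, or else up to 2 with the smallest p as values only, and counts of 5 or fewer genes past 0.05 over all genes were named in full for the fits of all libraries without a block, but not counts over a list alone or from alternatives. TPM1, IGFBP4, RHOB, C11orf96 and the genes of the blocked fits were named after their values were seen. In all, 231 list tests were made over classes and comparisons, of which 96 passed camera and 3 passed also with an estimated correlation. Which of these lists, and which of the 480 genes named by the rule, are described was decided after the results were seen, so the described lists are a selection and not a sample of all. All 3 lists that passed with an estimated correlation are described.

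The filters, marker lists, gene lists, tests, naming rule of genes and most alternatives were chosen before the data were examined. The alternatives added after seeing the data were a common floor of 4537 UMIs per cell, leaving out the 2 libraries of highest mitochondrial loss, the older format alone, the newer format alone for shares, counting a cytotoxic cluster as T cells, leave-one-out and format fits of gene lists, and settings of named genes beyond those planned.

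Lesional and perilesional libraries of the same site and number in their labels were taken as 3 pairs. Deviations from the group means of the paired libraries correlated at 0.560 to 0.695 in keratinocytes, 0.442 to 0.548 in fibroblasts, 0.504 to 0.727 in pericytes and 0.159 to 0.665 in all cells. The highest correlation among other combinations was 0.334, 0.338, 0.402 and 0.181. Every correlation of a pair passed 0.1, so the numbers were taken to pair the libraries, and paired libraries also share the matrix format. The fits carry no block, and a fit with the replicate block is an alternative. Other alternatives were DESeq2, its size factors in edgeR, no low count filter, the matrix format or the site as a term, the newer format alone, fits of the 2 groups compared alone, leaving out each library in turn, keeping doublet calls, clustering each library alone, leaving out genes among the 200 most abundant of another class and under 10% of that level in the tested one, stricter cell filters (500 genes, 10% mitochondrial), Leiden at 0.5 and 2, shares without epithelial cells, and edgeR on cell counts.

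Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.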

Results

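Skin of hidradenitis suppurativa, a chronic inflammatory disease of hair-bearing skin folds, was profiled by droplet single-cell RNA sequencing in 9 libraries. The libraries came from 4 lesional, 3 perilesional and 2 healthy samples of the axilla (4 libraries) or the groin (5 libraries). The values are counts of unique molecular identifiers (UMIs) per gene and cell barcode. Total UMIs per library were 7483725, 47509403, 27749835 and 34457473 in lesional replicates 1 to 4, and 7481412, 22203705 and 19447157 in perilesional replicates 1 to 3. Healthy replicates 1 and 2 held 49918852 and 31011991. After filtering, 32643 cells remained, from 1129 in lesional replicate 1 to 6809 in lesional replicate 2, with medians of 3334 to 8251 UMIs per cell. Lesional replicates 1 and 3 and perilesional replicates 1 and 2 were deposited in an older matrix format, and the other 5 libraries, both healthy ones included, in a newer format. The smallest barcode held 2349, 1874, 3622 and 4537 UMIs in lesional replicate 1, perilesional replicate 1, lesional replicate 3 and perilesional replicate 2, against 500 in each newer-format library. Cells under these minima are therefore absent from the older libraries, which limits shares and comparisons between formats. Within-format values stand beside many of the pooled ones, for healthy comparisons in the newer format alone, since no healthy library is in the older.

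Marker genes placed the cells in 12 named classes, with 11849 keratinocyte, 4597 vascular endothelial, 3999 pericyte or smooth muscle, 3955 fibroblast, 1656 plasma, 1425 B, 1362 macrophage or dendritic, 1188 T, 801 sweat gland, 167 melanocyte, 146 lymphatic endothelial and 101 erythrocyte cells. A further 1397 fell in 3 unnamed clusters. One, led by THY1, COL1A1 and TAGLN, held 3.47% ± 4.57 (SD, n = 4) of lesional, 0.210% ± 0.321 (n = 3) of perilesional and 0.0137% ± 0.0193 (n = 2) of healthy cells. Older-format lesional replicates 1 and 3 gave 45.6% and 45.2% of its 241 cells. Another, cytotoxic and led by CCL5, GNLY and NKG7 and not counted as T, held 1.32% ± 0.699 of lesional and 2.07% ± 3.48 of perilesional cells.

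The comparison of lesional with perilesional skin asks which cells and genes differ between a lesion and the skin beside it. Plasma cells, which secrete antibodies, made up 13.8% ± 10.6 (SD, n = 4) of lesional and 1.98% ± 1.69 (n = 3) of perilesional cells, a difference of 3.35 in mean log2 odds. B cells made up 8.09% ± 6.19 against 0.729% ± 0.95 (a difference of 3.72), and T cells 5.74% ± 3.73 against 2.77% ± 2.29 (1.5). Melanocytes, the pigment cells, stood at 0.0967% ± 0.0730 against 0.753% ± 0.0737 (a difference of -3.19), and their share was lower in lesional skin in each of the 3 pairs, while B, T and plasma cell shares were higher in 2 of the 3. Lesional replicate 4 held 0.0856% B cells, under the 0.384% of perilesional replicate 3 and the 1.80% of perilesional replicate 1. Keratinocytes were 27.8% ± 27.1 of lesional and 45.4% ± 13.7 of perilesional cells. Plasma cells reached 23.3% (95% Clopper-Pearson interval 20.9 to 25.9) in lesional replicate 1, 6.26% (5.69 to 6.86) in replicate 2, 22.7% (21.1 to 24.3) in replicate 3 and 3.15% (2.67 to 3.69) in replicate 4. The lowest of these lies under the 3.48% of perilesional replicate 3. Perilesional replicate 2 held 0 B cells among 1979, which allows a share of up to 0.152%, and lesional replicate 3 held 0 melanocytes among 2744, which allows up to 0.109%. These intervals and limits cover counting error only.

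With 1 library left out, the difference ran from 2.00 (without perilesional replicate 2) to 4.18 (without perilesional replicate 3) for plasma cells, from 2.02 (without perilesional replicate 2) to 5.45 (without lesional replicate 4) for B cells and from 0.20 (without perilesional replicate 2) to 2.28 (without perilesional replicate 3) for T cells. No class passed the exact permutation test over 35 splits of the 7 libraries, whose lowest possible p is 0.0286. The test ignores the pairs and gave 0.0857 for plasma cells and 0.0571 for melanocytes (adjusted 0.52 each). Within pairs (8 splits), p cannot go below 0.25. The plasma cell difference was 5.52 among the older-format libraries (22.98% against 1.24%) and 0.37 among the newer ones (4.70% against 3.48%). The T cell difference turned from 3.30 in the older to -1.07 in the newer format, against 5.43 and 1.71 for B cells and -3.66 and -2.68 for melanocytes. Keratinocytes differed by -4.20 in the older and 0.81 in the newer format.

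**Figure D1:**
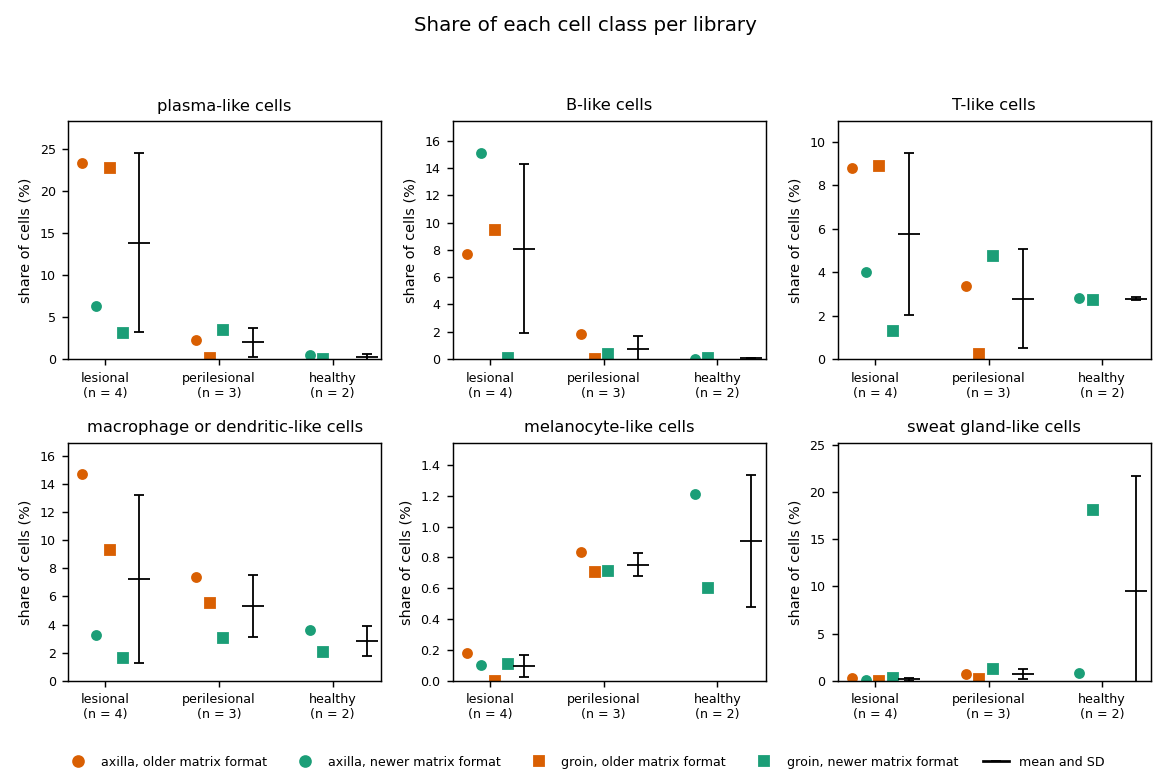
Share of cells per library (percent, y axis) for 6 cell classes in lesional (n = 4), perilesional (n = 3) and healthy (n = 2) skin. Each point is a library, circles are axilla and squares groin, orange marks the older and green the newer matrix format, and the black dash and bar give the mean and SD. Plasma cells reached 23.3% and 22.7% in the older-format lesional libraries, and sweat gland cells averaged 9.47% of healthy cells.

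Comparisons with healthy skin ask how diseased and adjacent skin differ from skin of unaffected donors. Healthy libraries held 0.254% ± 0.320 plasma cells (n = 2), 0.0565% ± 0.0361 B cells and 2.78% ± 0.0613 T cells. The lesional shares exceeded these by 6.38 in mean log2 odds for plasma cells, and all 4 lesional libraries lay above both healthy ones. Sweat gland cells were 0.169% ± 0.150 of lesional, 0.716% ± 0.568 of perilesional and 9.47% ± 12.2 of healthy cells, a lesional difference of -5.23. Melanocytes were 0.905% ± 0.429 of healthy cells, a lesional difference of -3.36. With 15 splits, the exact permutation test cannot go below 0.0667, which these 3 classes reached (adjusted p = 0.289), and with 10 splits it cannot go below 0.1 for perilesional against healthy skin. In the newer format alone the lesional differences were 5.04 for plasma cells, -4.60 for sweat gland cells and -2.94 for melanocytes. With edgeR on cell counts, the adjusted p was 0.00269 for sweat gland, 0.0138 for B and 0.0163 for plasma cells. The sweat gland difference was -2.88 without healthy replicate 2, which held 662 of these cells, and -7.58 without healthy replicate 1, which held 54.

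In keratinocytes, type I interferon genes were higher in lesional than in perilesional skin. The list rose as a set, with a median log2 fold change of 1.60 over 19 measured genes (camera adjusted p = 1.04e-25, and adjusted p = 0.00839 with an estimated correlation; fry adjusted p = 0.00987). EPSTI1, an interferon-induced gene of epithelial cells, stood at 14.2 ± 7.36 CPM (UMIs scaled to 1e+06 per sum; SD, n = 4) against 1.54 ± 0.707 (n = 3), a log2 fold change of 3.19 ± 0.59 (SE). IFI6, an interferon-induced mitochondrial protein, stood at 64.8 ± 20.2 against 9.41 ± 6.62 CPM, a log2 fold change of 2.81 ± 0.56. Neither gene passed over all genes (edgeR adjusted p = 0.809 each), and 8 of the 19 were higher when adjusted over the list alone. Within the newer format the log2 fold changes were 2.14 for EPSTI1 and 2.69 for IFI6, and within the older format 4.10 and 3.04.

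Keratinocyte genes of alarm and hyperproliferation, made in wounded and inflamed epidermis, had a median log2 fold change of 1.79 over 24 genes (camera adjusted p = 8.11e-14). That call was lost with the estimated correlation (adjusted p = 0.181 with an estimated correlation), and 3 genes were higher when adjusted over the list alone. The wound keratins KRT6A and KRT6C gave log2 fold changes of 3.08 ± 0.67 and 6.66 ± 1.41, and reads of these near-identical genes can be split uncertainly between them. KRT6A gave 1.79 within the newer and 3.81 within the older format, and KRT6C 2.89 and 9.39. Epidermal differentiation genes had a median of -1.45 over 17 genes (camera adjusted p = 1.17e-08, adjusted p = 0.0964 with an estimated correlation). Examples are CALML5, a calcium-binding protein of the upper epidermis, at -2.57 ± 0.79 (-1.60 without perilesional replicate 1) and the desmosomal cadherin DSC1 at -1.60 ± 0.53. Proliferation genes had a median of 1.06 over 18 (camera adjusted p = 5.76e-11, adjusted p = 0.181 with an estimated correlation), with the mitotic genes UBE2C at 1.40 ± 0.41 and CCNB1 at 1.73 ± 0.54. Interferon gamma genes had a median of 0.45 over 16 (camera adjusted p = 9.34e-07, adjusted p = 0.0964 with an estimated correlation), with APOL1 at 1.64 ± 0.43 and UBE2L6 at 1.01 ± 0.32. Within the newer and the older format, the medians were -1.41 and -1.22 for differentiation, 1.72 and 0.48 for proliferation and 1.01 and 0.70 for interferon gamma genes.

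With edgeR, 0 single keratinocyte genes passed, with 629 at an unadjusted p under 0.05, and DESeq2 called 31. With the replicate block, which compares the 3 pairs, 11 genes passed. CXCL1, a neutrophil-attracting chemokine, rose by 4.76 ± 0.31 (edgeR adjusted p = 0.00174) and SPRR2A, a cornified envelope protein, by 3.78 ± 0.28 (adjusted p = 0.00237). PDPN, CRCT1, SPRR2E, IFITM1 and RAB31 also rose, and KRT77, FABP4, SCEL and IGFL3 fell. FABP4 is also a leading gene of endothelial and KRT77 of sweat gland clusters, so their RNA is not excluded. These 11 were chosen after their values were seen. In the blocked fit the interferon list kept its median (1.56) but had an adjusted p = 0.229 with an estimated correlation. That p was 0.204 in the newer and 0.368 in the older format, with medians of 1.62 and 1.52. It was 0.0558 without lesional replicate 3 and 0.0834 without perilesional replicate 3, and under 0.05 without any other 1 library. Different clusters held most keratinocytes, by library as much as by group. A cluster led by KRT15 and KRT14 held 13% to 36.5% of lesional keratinocytes, 1 led by SERPINB2 and SFN held 74.3% in perilesional replicate 2 and at most 14.1% in the other perilesional libraries, and 1 led by KRT1 and KRT10 held 50.1% and 23.3% in healthy replicates 1 and 2. A cluster led by the alarm genes S100A7, S100A8 and KRT6A held 55.5%, 20.5%, 56.5% and 7.62% of keratinocytes in lesional replicates 1 to 4. It held 54.5%, 1.41% and 1.78% in perilesional replicates 1 to 3 and 0.255% and 0.83% in the healthy ones.

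Against healthy skin, lesional keratinocytes again had higher type I interferon genes, with a median log2 fold change of 2.14 over 19 genes, 14 of them higher when adjusted over the list alone. The list rose as a set (camera adjusted p = 3.35e-23, and adjusted p = 0.0157 with an estimated correlation). IFI27, a strongly interferon-induced gene, stood at 952 ± 700 CPM (n = 4) against 27.7 ± 4.97 (n = 2), a log2 fold change of 5.10 ± 0.94, and EPSTI1 at 4.08 ± 0.71. Alarm genes had a median of 6.03, with 21 of 24 higher when adjusted over the list alone (camera adjusted p = 6.49e-28, adjusted p = 0.0847 with an estimated correlation). The protease inhibitor SERPINB4, which has a near-identical neighbour, stood at 894 ± 900 against 6.37 ± 1.43 CPM (7.13 ± 1.66), and KRT6A at 4.03 ± 0.85. Interferon gamma genes had a median of 1.05 (camera adjusted p = 5.12e-07, adjusted p = 0.0847 with an estimated correlation), with APOL1 at 2.5 ± 0.52 and UBE2L6 at 1.46 ± 0.38. No gene passed with edgeR (0, with 1045 at an unadjusted p under 0.05), and DESeq2 called 154, IFI27, EPSTI1, SERPINB4, KRT6A, APOL1 and UBE2L6 among them. In the newer format alone the medians were 2.25 for type I interferon (adjusted p = 0.117 with an estimated correlation), 3.56 for alarm genes and 0.69 for interferon gamma genes. The interferon list had an adjusted p with an estimated correlation of 0.0708 without healthy replicate 1 and 0.0558 without lesional replicate 4. Sweat gland markers moved with these genes in the keratinocyte sums, with a median of -4.86 and 10 of 10 lower when adjusted over the list alone (adjusted p = 0.282 with an estimated correlation).

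Perilesional keratinocytes had alarm genes at a median of 4.12 above healthy ones (camera adjusted p = 2.14e-13, adjusted p = 0.488 with an estimated correlation). SERPINB4 gave 5.10 ± 1.51 (edgeR adjusted p = 0.83; 3.31 without perilesional replicate 1) and the T cell-attracting chemokine CCL20 6.17 ± 1.90. Within the newer format the list median was 1.74, SERPINB4 gave 3.99 and CCL20 0.03. With edgeR 0 genes passed, with 670 at an unadjusted p under 0.05, and DESeq2 called 16.

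**Figure D2:**
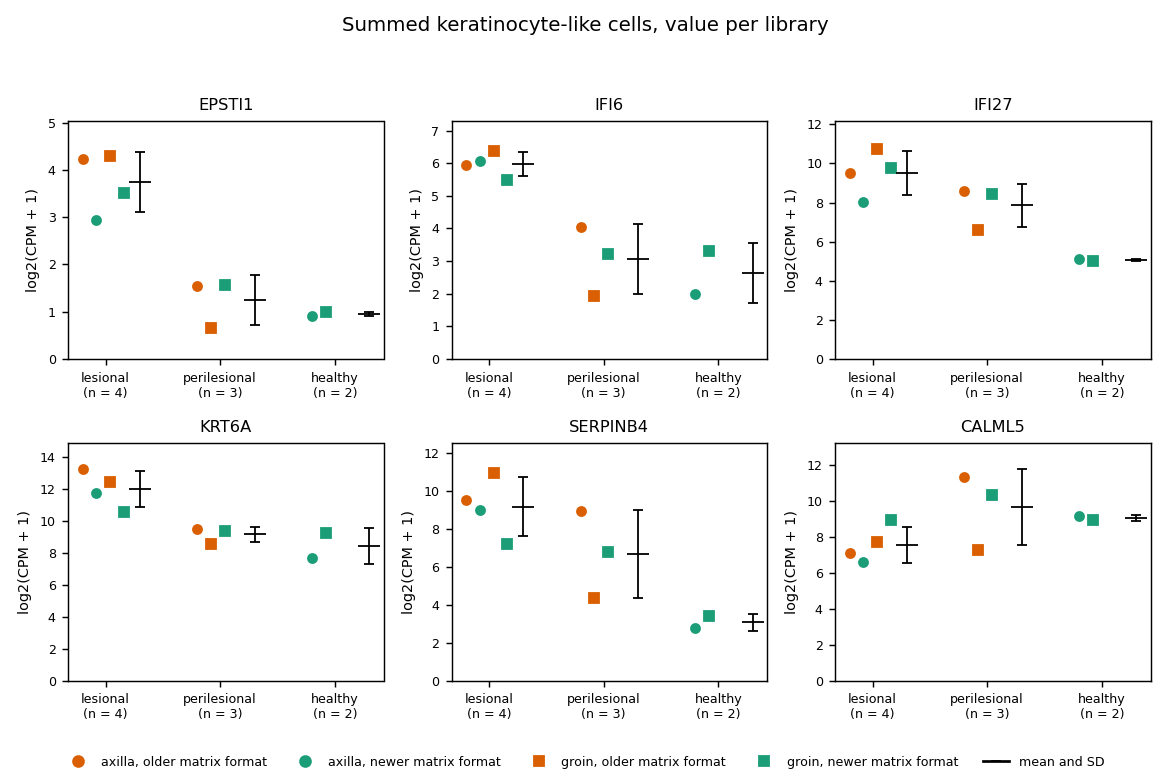
Values per library, as log2(CPM + 1) on the y axis, of 6 genes in summed keratinocytes of lesional (n = 4), perilesional (n = 3) and healthy (n = 2) skin. Symbols and colours are as in the plot of class shares, with mean and SD in black. The mean of IFI6 was 64.8 CPM in lesional and 9.41 CPM in perilesional skin.

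In fibroblasts, lesional skin had extracellular matrix and myofibroblast genes at a median of 0.93 above perilesional skin over 24 genes (camera adjusted p = 1.53e-07, adjusted p = 0.563 with an estimated correlation). ADAM12, a metalloprotease of activated fibroblasts, gave 2.98 ± 1.02 (4.66 without perilesional replicate 1) and the collagen COL6A3 1.23 ± 0.43. Against healthy skin the matrix median was 1.42 (camera adjusted p = 9.41e-09, adjusted p = 0.224 with an estimated correlation), with ADAM12 at 5.58 ± 1.38 and the collagen COL5A1 at 1.88 ± 0.54. Inflammatory fibroblast genes had a median of 5.58 over 18, with 2 higher when adjusted over the list alone (camera adjusted p = 7.47e-08, adjusted p = 0.375 with an estimated correlation). The matrix-degrading protease MMP3 stood at 577 ± 735 CPM (n = 4) against 1.85 ± 0.512 (n = 2), a log2 fold change of 8.15 ± 2.09, and the cytokine IL11 gave 5.67 ± 1.56 (edgeR adjusted p = 0.323 each).

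MHC class II genes, which present antigen to helper T cells, had a median of 1.46 in lesional over healthy fibroblasts, with 7 of 8 higher when adjusted over the list alone (camera adjusted p = 1.97e-08, adjusted p = 0.171 with an estimated correlation). HLA-DQA1 gave 2.65 ± 0.74 and HLA-DPA1 1.41 ± 0.44, and these polymorphic genes are uncertain against a single reference sequence. Chemokines of a 12-gene tertiary lymphoid list had a median of 2.65 over 8 genes (camera adjusted p = 0.000956, adjusted p = 0.375 with an estimated correlation), with the leukocyte attractants CCL5 at 3.07 ± 1.05 and CCL3 at 5.59 ± 2.17. CCL3 gave 3.62 without healthy replicate 1 and 8.51 without healthy replicate 2. Genes of lymphoid organisation had a median of 1.69 over 12 (camera adjusted p = 0.0429, adjusted p = 0.439 with an estimated correlation), with the adhesion molecule VCAM1 at 1.99 ± 0.71 (1.18 without healthy replicate 1 and 3.25 without healthy replicate 2). Plasma cell markers (2.22) and macrophage markers (1.5) were also higher in these lesional fibroblast sums. In perilesional over healthy fibroblasts the MHC class II median was 1.61, with 4 of 8 higher when adjusted over the list alone (camera adjusted p = 2.85e-10, adjusted p = 0.0902 with an estimated correlation). There HLA-DRB1 gave 2.21 ± 0.55 and the invariant chain CD74 1.73 ± 0.50, and macrophage markers had a median of 0.90. Inflammatory genes had a median of 3.46 (camera adjusted p = 6.86e-06, adjusted p = 0.575 with an estimated correlation), with CXCL1 at 5.25 ± 1.97.

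With edgeR, 0 fibroblast genes passed in the 3 comparisons. At an unadjusted p under 0.05 there were 516 for lesional against perilesional, 937 for lesional against healthy and 403 for perilesional against healthy skin, and DESeq2 called 11, 121 and 10. Without healthy replicate 1, 5 genes passed for lesional against healthy skin, 10 without lesional replicate 4 and 1 without lesional replicate 2, and 8 in the newer format alone. With the replicate block, 1 gene passed for lesional against perilesional skin, SGCA, a sarcoglycan of muscle, which fell by 7.17. Within the newer format, the lesional against perilesional matrix median was 0.67, and 0.98 in the older. Newer-format medians for lesional against healthy skin were 1.19 for matrix, 2.58 for inflammatory, 1.5 for MHC class II, 0.59 for chemokine and 0.34 for lymphoid organisation genes. For perilesional against healthy skin they were 1.41 for MHC class II and -0.75 for inflammatory genes, and CXCL1 turned to -0.18. Fibroblast clusters differed between libraries of a group. A cluster led by COL1A1 and COL3A1 held 81.3% of fibroblasts in lesional replicate 3 and 0 cells in lesional replicate 4, 1 led by DCN and PTGDS held 89.1% in perilesional replicate 2 and 1.11% in perilesional replicate 3, and 1 led by COL1A2 and COL1A1 held 55.6% and 4.90% in healthy replicates 1 and 2.

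In pericytes and smooth muscle cells, which line small vessels, 12 genes fell and 2 rose in lesional against healthy skin, and 4 of those that fell belong to a list of 17 immediate early genes. KLF2, a transcription factor of vascular quiescence (ENSG00000127528), fell by 4.38 ± 0.43 on the log2 scale, from 917 ± 563 CPM in healthy (n = 2) to 43.9 ± 13 in lesional skin (n = 4, adjusted p = 0.00171). CEBPD, an acute-phase transcription factor (ENSG00000221869), fell by 3.88 ± 0.41 (adjusted p = 0.00202), and JUN, a subunit of AP-1, by 3.41 ± 0.45, from 4342 ± 186 to 408 ± 210 CPM (adjusted p = 0.0107). IER2 (-3.58 ± 0.45), MAFF (-3.96 ± 0.58), GFOD1 (-3.58 ± 0.48), EGR1 (-2.94 ± 0.48) and the phosphatase DUSP1 (-2.54 ± 0.41, and -1.46 without healthy replicate 2) also fell. FN1, the matrix protein fibronectin, rose by 2.58 ± 0.43, from 53.8 ± 17.9 to 322 ± 118 CPM (adjusted p = 0.041), and the serine protease PRSS23 by 2.35 ± 0.34 (adjusted p = 0.0152). DESeq2 called 65 against these 14 of edgeR. With a common floor of 4537 UMIs per cell, 9 of the 14 passed, and without the 2 libraries of highest mitochondrial loss 8 passed, KLF2, CEBPD and JUN among them both times.

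The immediate early list, which also marks tissue handling, had a median of -1.92 over 17 genes, with 4 that fell over all genes and 6 adjusted over the list alone (camera adjusted p = 9.31e-14, adjusted p = 0.0922 with an estimated correlation). Matrix genes had a median of 1.07 over 22 genes, with FN1 past 0.05 over all genes and 10 higher when adjusted over the list alone (camera adjusted p = 7.05e-10, adjusted p = 0.0797 with an estimated correlation). Fibroblast markers had a median of 0.74 and vascular endothelial markers -0.72 in the same sums. In the newer format alone the medians were -3.13 for immediate early and 1.13 for matrix genes, and all 14 genes were past 0.05 there. KLF2 and CEBPD passed in each of the 6 fits that left out 1 library. The count was 2 without healthy replicate 2, 2 without lesional replicate 4, 6 without lesional replicate 2 and 8 without lesional replicate 1. Without healthy replicate 2 the adjusted p was 0.0883 for JUN, IER2 and MAFF, 0.243 for GFOD1, 0.407 for PRSS23, 0.472 for EGR1, 0.671 for FN1 and 1.00 for DUSP1. Without lesional replicate 4 it was 0.0502 for JUN, IER2 and FN1, 0.0647 for GFOD1 and PRSS23, 0.146 for MAFF and DUSP1 and 0.152 for EGR1. FN1 and EGR1 passed in none of the 6 fits, MAFF only without lesional replicate 3 and DUSP1 only without healthy replicate 1, and JUN failed also without lesional replicate 1 (0.0607), GFOD1 without lesional replicate 2 (0.0723), and PRSS23 without lesional replicate 2 (0.0574) or healthy replicate 1 (0.207). Where 1 healthy library is left, it is assumed to vary like the other groups.

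In perilesional against healthy pericytes 8 genes fell. KLF2 fell by 4.30 ± 0.48 and CEBPD by 3.88 ± 0.46 (adjusted p = 0.00732 each), JUN by 3.83 ± 0.51 (adjusted p = 0.0201), and IER2 (-3.21 ± 0.50), the histone gene H2AFX (-3.06 ± 0.50) and DUSP1 (-2.85 ± 0.46, and -1.76 without healthy replicate 2) at an adjusted p of 0.0496 each. RHOB and C11orf96 made up the 8 genes called by edgeR, and DESeq2 called 27. With the common UMI floor 1 of the 8 passed, JUN, and without the 2 libraries of highest mitochondrial loss 0 passed. The immediate early list had a median of -1.45, with 3 that fell over all genes and 4 adjusted over the list alone (camera adjusted p = 4.12e-09, adjusted p = 0.357 with an estimated correlation), and -4.00 in the newer format. Without healthy replicate 2 the count was 2, without perilesional replicate 1 it was 5, without replicate 2 it was 1 and without replicate 3 it was 3. CEBPD passed in each fit, and KLF2 in each but the one without perilesional replicate 2 (adjusted p = 0.0525). H2AFX passed in none of the 5 fits, IER2 only without perilesional replicate 3, and JUN and DUSP1 failed without healthy replicate 2 (0.143 and 0.999), perilesional replicate 2 (0.131 and 0.255) or perilesional replicate 3 (0.0874 and 0.235).

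Lesional against perilesional pericytes had matrix genes at a median of 0.68 over 22, with 5 higher when adjusted over the list alone (camera adjusted p = 3.81e-06, adjusted p = 0.246 with an estimated correlation). The collagens COL3A1 and COL5A2 gave 1.67 ± 0.44 and 1.62 ± 0.43. With the replicate block, 14 genes passed, and COL3A1 (1.36 ± 0.20, adjusted p = 0.00183), COL5A2 (1.21), COL1A1 (1.23) and the acute-phase gene SAA1 (2.18) rose, while the cytokine IL6 fell by 2.58 ± 0.30 (adjusted p = 0.000568) and the chemokine CXCL3 by 2.17. COL1A1, SAA1, IL6, CXCL3 and the erythrocyte gene HBA2 (-4.49) were chosen after their values were seen. Without the block, edgeR called 0, with 237 at an unadjusted p under 0.05, and DESeq2 called 1, and without perilesional replicate 3 edgeR called 1. The matrix median was 1.16 in the newer and 0.082 in the older format. Pericyte clusters also differed between libraries. A cluster led by RGS5 with TAGLN held 651 cells. Healthy replicates 1 and 2 gave 46.5% and 16.9% (of 654 and 440 class cells). Older-format perilesional replicates 1 and 2 gave 16.4% and 4.30% (of 198 and 43). Lesional replicates 1 and 3 gave 5.07% and 10.3% (of 89 and 114). It was scarce only in the newer-format diseased libraries (at most 0.307%). A cluster led by RGS5 with ACTA2 held 89.3% and 44.2% of the class in lesional replicates 2 and 4 and at most 16.9% in replicates 1 and 3. The cluster led by ACTA2 held 62.0% in perilesional replicate 3 and at most 11.6% in replicates 1 and 2.

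**Figure D3:**
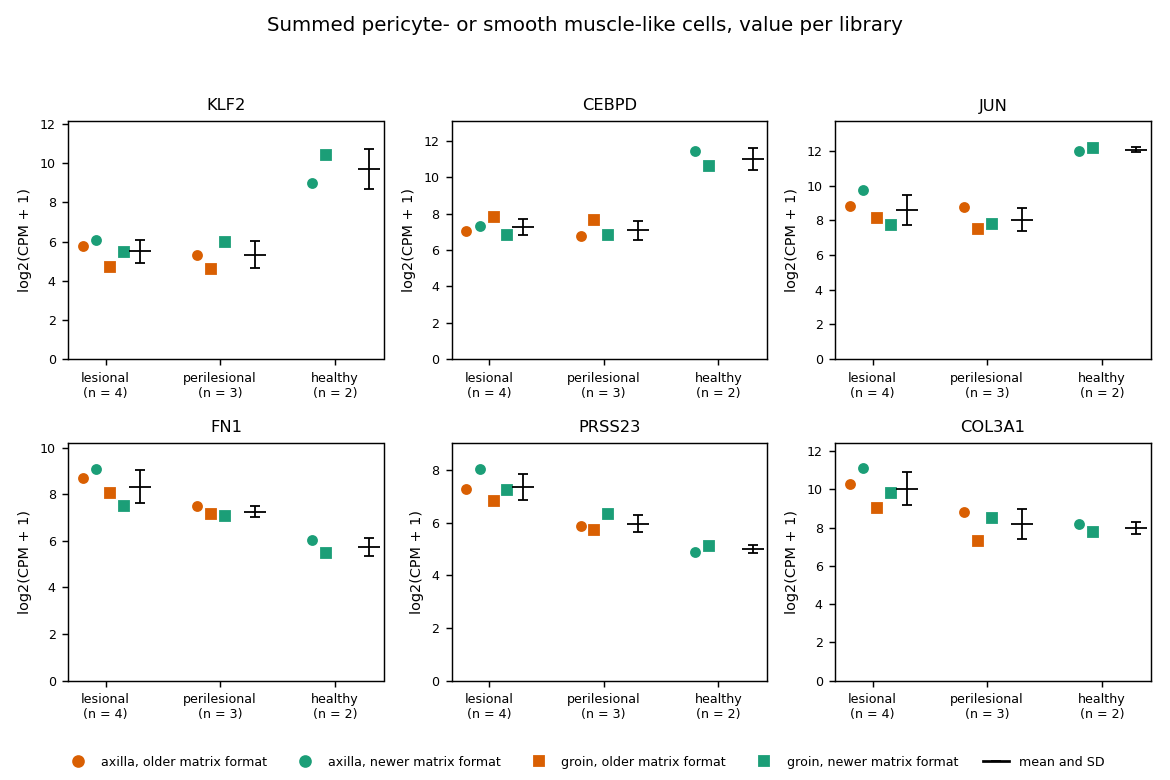
Values per library, as log2(CPM + 1) on the y axis, of 6 genes in summed pericytes and smooth muscle cells of lesional (n = 4), perilesional (n = 3) and healthy (n = 2) skin. Symbols and colours are as in the plot of class shares, with mean and SD in black. JUN averaged 4342 CPM in healthy and 408 CPM in lesional skin.

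In macrophages and dendritic cells, 8 genes fell in lesional against healthy skin, LYVE1 of a list of 13 resident macrophage genes among them. LYVE1, a hyaluronan receptor of perivascular macrophages (ENSG00000133800), fell by 8.35 ± 0.73 on the log2 scale, from 315 ± 23.6 CPM in healthy (n = 2) to 0.755 ± 0.968 in lesional skin (n = 4, adjusted p = 0.00153). The fatty acid receptor CD36 fell by 3.35 ± 0.43, from 250 ± 33.2 to 23.8 ± 12.6 CPM (adjusted p = 0.0204), and PDK4, a brake on glucose oxidation, by 5.42 ± 0.71 (adjusted p = 0.0204). The lipid transporter ABCA6 (-4.29 ± 0.58), TCHH (-4.08 ± 0.57), TPM1 and IGFBP4 also fell. MAMDC2 fell too (adjusted p = 0.0204), with 0 UMIs in lesional skin, which is at least 101-fold lower than its healthy mean of 64.6 unscaled CPM, against a floor of 3 counts over the group. These 8 were all the genes called by edgeR, and DESeq2 called 35. With the common floor of 4537 UMIs per cell, which left 57 and 26 healthy cells of this class, 0 of the 8 passed, and LYVE1 was at -7.54 ± 0.94 (adjusted p = 0.0944). Without the 2 libraries of highest mitochondrial loss, 2 of the 8 passed, LYVE1 and TCHH. Resident macrophage genes had a median of -2.48 over 13, with LYVE1 past 0.05 over all genes and 6 lower when adjusted over the list alone (camera adjusted p = 6.47e-14, adjusted p = 0.124 with an estimated correlation). A cluster led by RNASE1, C1QA and C1QC held 66.7% and 53.9% of this class in healthy replicates 1 and 2, and at most 11.7% in the perilesional and 1.80% in the lesional libraries. Its cells had a median of 1641 UMIs, under the smallest barcode of each older-format library, so only newer-format libraries can be compared for it, and lesional replicates 2 and 4 held 4 and 0 of its cells. Clusters led by LYZ with HLA-DQA1 and by LYZ with CCL18 held nearly all lesional cells of the class. Of the latter's 430 cells, lesional replicates 1 to 4 gave 30.9%, 7.91%, 42.3% and 2.56%.

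Interferon gamma genes were at a median of 1.73 in lesional over healthy cells of this class (camera adjusted p = 2.88e-08, adjusted p = 0.169 with an estimated correlation), with the guanylate-binding proteins GBP1 at 4.01 ± 1.09 and GBP5 at 4.52 ± 1.62. Mature dendritic genes had a median of 1.26 with 1 higher when adjusted over the list alone (camera adjusted p = 0.00277, adjusted p = 0.124 with an estimated correlation; fry adjusted p = 0.0195), with the costimulator CD80 at 3.0 ± 0.81 and LAMP3 at 1.64 ± 0.66. Inflammatory myeloid genes had a median of 1.12 with 1 higher when adjusted over the list alone (camera adjusted p = 0.000588, adjusted p = 0.593 with an estimated correlation). S100A8 gave 5.17 ± 0.93 and S100A12 3.98 ± 1.28. Neutrophil markers, which include both, had a median of 3.98 in these sums. Keratinocyte markers had a median of -1.69. In the newer format alone, all 8 genes were past 0.05, and the medians were -4.02 for resident macrophage, 0.85 for interferon gamma, 1.21 for mature dendritic and 0.52 for inflammatory myeloid genes. The number of genes past 0.05 was 3 without healthy replicate 1, 1 without healthy replicate 2, 1 without lesional replicate 1, 1 without lesional replicate 2 and 2 without lesional replicate 3, and LYVE1 passed in each. Without healthy replicate 2 the adjusted p of CD36, PDK4, ABCA6, TCHH and MAMDC2 was 0.143 each. MAMDC2, ABCA6 and TCHH passed only without lesional replicate 4, PDK4 only without healthy replicate 1, and CD36 without lesional replicate 3 or 4.

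Perilesional cells of this class had resident macrophage genes at a median of -2.78 against healthy ones, with 4 lower when adjusted over the list alone (camera adjusted p = 1.74e-12, adjusted p = 0.276 with an estimated correlation). LYVE1 fell by 6.94 ± 0.80 (adjusted p = 0.0214), the 1 gene called by edgeR, and DESeq2 called 36. It did not pass with the common UMI floor (-5.43 ± 1.1, adjusted p = 0.981). Mature dendritic genes rose as a set, with a median of 2.49 over 13 (camera adjusted p = 2.27e-05, and adjusted p = 0.0348 with an estimated correlation; fry adjusted p = 0.00334). CCR7, their homing receptor, gave 3.44 ± 1.04, and the cytokine subunit EBI3 2.61 ± 0.81 (1.70 without perilesional replicate 3). The LYZ with HLA-DQA1 cluster held 77.4% of pooled perilesional and 33.2% of pooled healthy cells, so a changed mix is not excluded. In the newer format alone the medians were -2.86 for resident macrophage and 1.03 for mature dendritic genes, with CCR7 at 1.36 and EBI3 at 3.62. LYVE1 had an adjusted p of 0.0694 without healthy replicate 1, 0.124 without healthy replicate 2, 0.0979 without perilesional replicate 1, 0.104 without replicate 2 and 0.101 without replicate 3. The mature dendritic list had an adjusted p with an estimated correlation of 0.0893 without healthy replicate 1, 0.0924 without healthy replicate 2, 0.0713 without perilesional replicate 2 and 0.127 without replicate 3.

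Lesional against perilesional cells of this class had interferon gamma genes at a median of 0.73 over 17 (camera adjusted p = 0.00234, adjusted p = 0.608 with an estimated correlation). GBP5 gave 4.68 ± 1.44 and GBP1 2.07 ± 0.80, and GBP1 was -0.20 in the newer and 3.28 in the older format, where the list medians were 0.082 and 1.27. Keratinocyte markers had a median of -1.98 in these sums, with 2 lower when adjusted over the list alone. With edgeR 0 genes passed, with 321 at an unadjusted p under 0.05, and DESeq2 called 3, and without perilesional replicate 3 edgeR called 2.

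**Figure D4:**
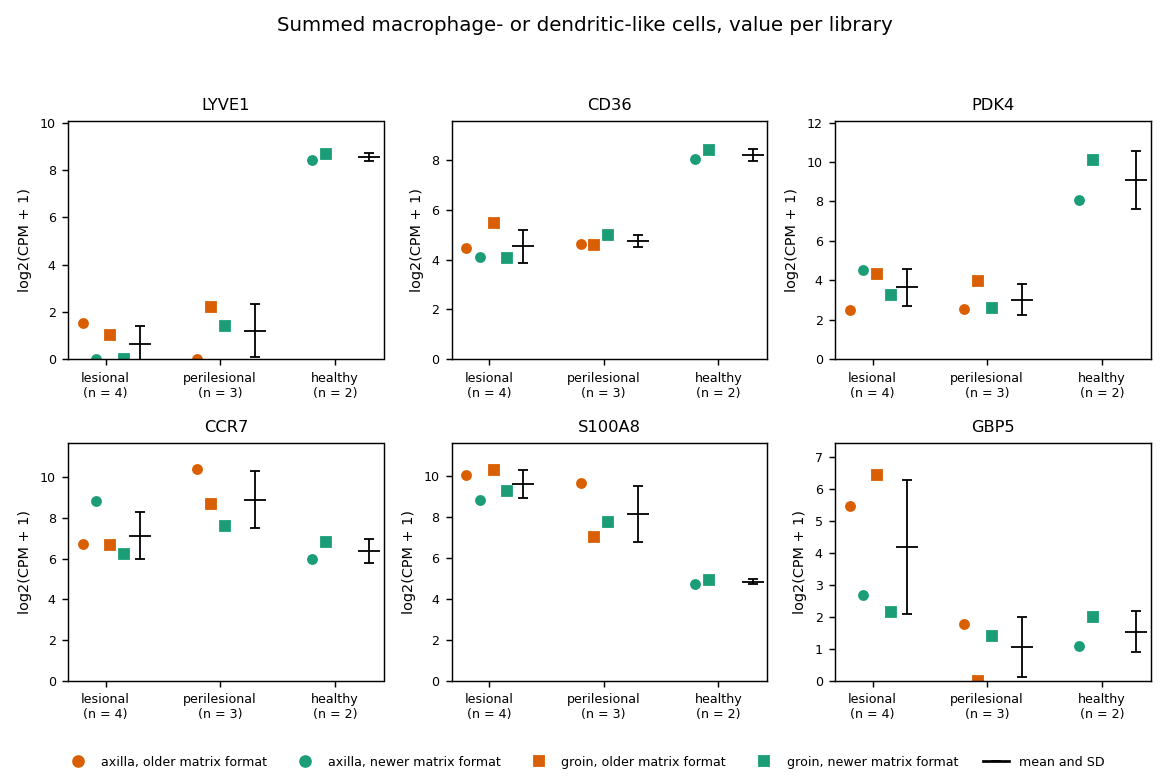
Values per library, as log2(CPM + 1) on the y axis, of 6 genes in summed macrophages and dendritic cells of lesional (n = 4), perilesional (n = 3) and healthy (n = 2) skin. Symbols and colours are as in the plot of class shares, with mean and SD in black. LYVE1 averaged 315 CPM in healthy and 0.755 CPM in lesional skin.

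In T cells, ANKRD28, a regulatory subunit of a protein phosphatase (ENSG00000206560), fell by 3.47 ± 0.35 in lesional (n = 4) against healthy skin (n = 2), from 705 ± 90.0 to 64.4 ± 10.2 CPM (adjusted p = 0.00496). It was the 1 gene called by edgeR and passed without any 1 library, but not with each library clustered alone (-3.08 ± 0.44, adjusted p = 0.0833), and DESeq2 called 83. Interferon gamma genes had a median of 1.30, with 6 of 10 higher when adjusted over the list alone (camera adjusted p = 0.00318, adjusted p = 0.475 with an estimated correlation). GBP5 gave 3.05 ± 0.66 (edgeR adjusted p = 0.0905) and GBP2 1.66 ± 0.50 (2.5 without healthy replicate 2). Proliferation genes had a median of 2.99 over 18, with 1 higher when adjusted over the list alone (camera adjusted p = 9.57e-08, adjusted p = 0.475 with an estimated correlation), with CCNB1 at 4.71 ± 1.12 (7.86 without healthy replicate 1) and the kinetochore gene CENPF at 2.91 ± 0.86. A T cell cluster with the proliferation genes UBE2C and KIAA0101 among its leading genes held 42 of 99 T cells in lesional replicate 1, 32 of 273 in replicate 2, 20 of 244 in replicate 3 and 1 of 61 in replicate 4. It held 22 of 52 in perilesional replicate 1 and 0 of 172 in perilesional replicate 3, and 1 of 182 and 0 of 100 in the healthy ones. ANKRD28, in the newer format alone, gave -3.36 and the medians were 1.15 and 2.80. Without healthy replicate 1 the count was 5, without healthy replicate 2 it was 3 and without lesional replicate 2 it was 3. Against perilesional skin (n = 2 with at least 20 T cells), lesional interferon gamma genes had a median of 0.62 over 10 (camera adjusted p = 0.00092, adjusted p = 0.207 with an estimated correlation), with GBP5 at 1.46 ± 0.55 and GBP2 at 1.19 ± 0.48. That median was 0.32 in the newer and 1.19 in the older format. With edgeR 0 T cell genes passed for lesional against perilesional skin, with 105 at an unadjusted p under 0.05, DESeq2 called 1. The replicate block called 6, IL17F, which fell, and 5 genes made mainly by other cells (HBB, HBA2, KRT1, CALML5 and IGLL5). In T cells that block held 2 pairs only, too few to judge the spread between pairs well. For perilesional against healthy skin the counts were 0, 507 and 25, without a blocked fit.

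In vascular endothelial cells, genes of TNF and NF-kB signalling had a median of -0.76 over 14 in lesional against healthy skin (camera adjusted p = 0.0129, adjusted p = 0.567 with an estimated correlation), with the inhibitor NFKBIA at -1.63 ± 0.49 and the subunit RELB at -1.10 ± 0.38. Perilesional endothelium had immediate early genes at a median of -1.63 against healthy skin (camera adjusted p = 1.15e-05, adjusted p = 0.91 with an estimated correlation), with JUN at -2.48 ± 0.73 (-1.47 without healthy replicate 2) and JUNB at -2.07 ± 0.63. The newer format alone gave -1.64 for NFKBIA, -0.99 for RELB, -2.97 for JUN and -2.70 for JUNB. No endothelial gene passed with edgeR, with counts of 0 and, at an unadjusted p under 0.05, 669 for lesional against perilesional, 836 for lesional against healthy and 817 for perilesional against healthy skin. DESeq2 called 0, 139 and 35, and edgeR called 4 for lesional against healthy skin without healthy replicate 1 and 4 without lesional replicate 4. For lesional and for perilesional against healthy skin, edgeR called 184 and 47 genes in the newer format alone, and 145 and 4 with the matrix format as a term. A cluster led by VWF and PLVAP held 32.6% to 90.7% of endothelial cells in the lesional libraries, 1 led by FABP4 and SELE held 85.8%, 63.2% and 0 cells in perilesional replicates 1, 2 and 3, and 1 led by CLDN5 and DARC held 93.5% and 86.8% in the healthy ones. In plasma cells, edgeR called 0 genes for lesional against perilesional skin, with 75 at an unadjusted p under 0.05, and DESeq2 called 0.

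In the sum of all cells, the 12-gene chemokine list was higher in lesional than in healthy skin, with a median of 2.58 over 12 (camera adjusted p = 0.00515, adjusted p = 0.473 with an estimated correlation). CXCL9 and CXCL10, T cell-attracting chemokines induced by interferon gamma, gave 7.12 ± 2.30 and 5.62 ± 1.92, and 2.83 and 3.52 in the newer format alone. With edgeR, counts were 0 in each comparison, with 982, 2140 and 1242 at an unadjusted p under 0.05 for lesional against perilesional, lesional against healthy and perilesional against healthy skin, and DESeq2 called 21, 850 and 87. Between sites, HOXC10, a homeobox gene of the posterior body axis, was lower in axilla than in groin by -2.99 ± 0.25 (2.13 against 17.3 CPM, edgeR adjusted p = 0.0282, n = 4 and 5), the 1 gene called, and DESeq2 called 14. That call ended without any 1 library. In keratinocytes and fibroblasts edgeR called 0 site genes (419 and 246 at an unadjusted p under 0.05), and DESeq2 called 2 and 5. The test of whether the lesional change differed between sites gave 0 genes with edgeR, with 139 at an unadjusted p under 0.05, and DESeq2 called 2. The p-values measure the spread between these libraries, since the files do not say whether each came from a separate donor.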

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

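A gap test for a single library far from the other 3 of its group was set before the data were examined. It was applied to 77 measures of the 4 lesional libraries, the class shares and genes chosen for description after the results were seen, and 3 passed where chance marks about 1 in 20. No test of an explanation was run for them. Fibroblasts made up 33.1% of cells in lesional replicate 3 and between 2.23% and 5.40% in the other 3. HLA-DRB1, an antigen-presenting gene of high polymorphism, stood at 97.4 unscaled CPM in the fibroblast sum of lesional replicate 4 and between 32.3 and 41.6 CPM in the others. CCR7, a homing receptor of mature dendritic cells, stood at 448 unscaled CPM in the macrophage or dendritic sum of lesional replicate 2 and between 74.6 and 105 CPM in the others.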

How the results depend on the processing

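The alternatives were chosen beforehand, except those named under data processing as added later. Of 1441 recomputed log2 fold changes of named genes, 1248 kept direction and side of the threshold, which most genes had not passed. Another 143 no longer passed, 48 newly passed and 2 turned sign. These were CXCL1 in perilesional against healthy fibroblasts (-0.18) and GBP1 in lesional against perilesional macrophages or dendritic cells (-0.20), both in the newer format alone. Of 683 share differences, none of which had passed, 618 kept direction and side, 62 turned sign and 3 newly passed. Of 438 gene counts, 290 stayed within 1.5 times and 148 did not. Among the 14 pericyte genes of lesional against healthy skin, 14 were shared with the newer format alone, 12 with DESeq2, 9 with the common UMI floor and 8 with the fit without the 2 libraries of highest mitochondrial loss, and among the 8 macrophage or dendritic genes 8, 8, 0 and 2. Except where a setting holds fewer cells, genes or libraries, the cause was not tested. Where an arm was left with 1 library, it is assumed to vary like the others.

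DESeq2 gave 21 in all cells, 31 in keratinocyte, 11 in fibroblast, 1 in pericyte, 1 in T and 3 in macrophage or dendritic for lesional against perilesional, and 850 in all cells, 154 in keratinocyte, 121 in fibroblast, 65 in pericyte, 139 in vascular endothelial, 83 in T and 35 in macrophage or dendritic for lesional against healthy. It gave, for perilesional against healthy, 87 in all cells, 16 in keratinocyte, 10 in fibroblast, 27 in pericyte, 35 in vascular endothelial, 25 in T and 36 in macrophage or dendritic. It gave, for axilla against groin, 14 in all cells, 2 in keratinocyte and 5 in fibroblast. It gave, for the lesional effect in axilla against groin, 2 in all cells. The matrix format as a term gave 2 in keratinocyte for lesional against perilesional, and 2 in all cells, 1 in keratinocyte, 3 in fibroblast, 207 in pericyte, 145 in vascular endothelial, 6 in T and 29 in macrophage or dendritic for lesional against healthy. It gave, for perilesional against healthy, 1 in all cells, 1 in keratinocyte, 1 in fibroblast, 101 in pericyte, 4 in vascular endothelial and 23 in macrophage or dendritic. It gave, for axilla against groin, 9 in fibroblast. The replicate block gave 11 in keratinocyte, 1 in fibroblast, 14 in pericyte and, with 2 pairs only, 6 in T for lesional against perilesional. The newer-format libraries alone gave 1 in pericyte, 2 in T and 1 in macrophage or dendritic for lesional against perilesional, and 4 in keratinocyte, 8 in fibroblast, 282 in pericyte, 184 in vascular endothelial, 65 in T and 108 in macrophage or dendritic for lesional against healthy. It gave, for perilesional against healthy, 1 in keratinocyte, 1 in fibroblast, 161 in pericyte, 47 in vascular endothelial, 4 in T and 13 in macrophage or dendritic. The common UMI floor gave 8 in fibroblast for lesional against perilesional, and 2 in fibroblast and 0 in macrophage or dendritic for lesional against healthy, and 1 in pericyte and 0 in macrophage or dendritic for perilesional against healthy. Dropping the low count filter gave 13 in T, 54 in macrophage or dendritic and 3 in plasma for lesional against perilesional, and 28 in fibroblast, 44 in pericyte, 59 in vascular endothelial, 189 in T and 131 in macrophage or dendritic for lesional against healthy. It gave, for perilesional against healthy, 19 in pericyte, 2 in vascular endothelial, 45 in T and 112 in macrophage or dendritic. It gave, for axilla against groin, 2 in keratinocyte and 79 in fibroblast. Fits of the 2 groups compared alone gave 2 in fibroblast, 29 in pericyte, 12 in vascular endothelial, 46 in T and 1 in macrophage or dendritic for lesional against healthy, and 1 in fibroblast, 0 in pericyte and 0 in macrophage or dendritic for perilesional against healthy. Keeping the cells called by Scrublet gave 1 in fibroblast for lesional against healthy, and 4 in pericyte for perilesional against healthy. Leaving out the 2 libraries of highest mitochondrial loss gave 2 in vascular endothelial and 6 in T for lesional against perilesional, and 92 in fibroblast, 17 in vascular endothelial, 159 in T and 3 in macrophage or dendritic for lesional against healthy. It gave, for perilesional against healthy, 0 in pericyte, 10 in T and 0 in macrophage or dendritic. DESeq2 size factors in edgeR gave 4 in pericyte for perilesional against healthy. The site as a term gave 9 in T for lesional against healthy, and 4 in pericyte and 0 in macrophage or dendritic for perilesional against healthy. Clustering each library alone gave 0 in T for lesional against healthy, and 3 in pericyte and 2 in macrophage or dendritic for perilesional against healthy. The older-format libraries alone gave 31 in T for lesional against perilesional. Leaving out genes abundant in other classes gave 2 in T for lesional against healthy.

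With 1 library left out, the count for lesional against perilesional was 0 to 1 in pericyte (highest without perilesional replicate 3), 0 to 2 in vascular endothelial (highest without perilesional replicate 3), 0 to 2 in T (highest without perilesional replicate 1) and 0 to 2 in macrophage or dendritic (highest without perilesional replicate 3). The same count for lesional against healthy was 0 to 1 in keratinocyte (highest without lesional replicate 2), 0 to 10 in fibroblast (highest without lesional replicate 4), 2 to 14 in pericyte (highest without healthy replicate 1), 0 to 4 in vascular endothelial (highest without healthy replicate 1 and lesional replicate 4), 1 to 5 in T (highest without healthy replicate 1) and 1 to 6 in macrophage or dendritic (highest without lesional replicate 4). The same count for perilesional against healthy was 1 to 8 in pericyte (highest without healthy replicate 1), 0 to 2 in vascular endothelial (highest without healthy replicate 1) and 0 to 1 in macrophage or dendritic (highest without perilesional replicate 3). The same count for axilla against groin was 0 in all cells, 0 to 1 in keratinocyte (highest without healthy replicate 1 and healthy replicate 2) and 0 to 2 in fibroblast (highest without lesional replicate 3).

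The newer-format libraries alone turned the sign of keratinocyte (0.81), T (-1.07), macrophage or dendritic (-0.41) and unnamed (-0.93) for lesional against perilesional, and of keratinocyte (1.21), pericyte (0.042), T (-0.28), macrophage or dendritic (-0.25), erythrocyte (0.060) and unnamed (-0.47) for lesional against healthy. The same setting turned pericyte (1.91), T (0.79), erythrocyte (1.18) and unnamed (0.47) for perilesional against healthy. The older-format libraries alone turned the sign of fibroblast (0.045), pericyte (0.093), vascular endothelial (-1.0) and lymphatic endothelial (-0.16) for lesional against perilesional. The common UMI floor turned the sign of pericyte (0.81), vascular endothelial (-0.27) and lymphatic endothelial (-0.0050) for lesional against perilesional, and of erythrocyte (1.06) for lesional against healthy. The same setting turned T (2.52) and erythrocyte (2.16) for perilesional against healthy. Leaving out the 2 libraries of highest mitochondrial loss turned the sign of pericyte (0.21), vascular endothelial (-0.32) and erythrocyte (0.89) for lesional against perilesional. Shares without keratinocyte and sweat gland cells turned the sign of vascular endothelial (-0.058) and macrophage or dendritic (-0.33) for lesional against perilesional, and of fibroblast (0.11), pericyte (0.19) and melanocyte (0.043) for perilesional against healthy. The replicate block turned the sign of vascular endothelial (-0.15) for lesional against perilesional. Clustering each library alone turned the sign of lymphatic endothelial (-0.92) and macrophage or dendritic (-0.0069) for lesional against perilesional. Leiden at 2 turned the sign of erythrocyte (0.014) for lesional against perilesional. edgeR on cell counts turned the sign of pericyte (0.49) for perilesional against healthy. The differences passed 0.05 by edgeR for sweat gland (-5.82), B (7.12) and plasma (5.72) cells of lesional against healthy skin. A minimum of 500 genes and at most 10% mitochondrial UMIs turned the sign of erythrocyte (0.58) for lesional against healthy, and of erythrocyte (1.04) for perilesional against healthy. Leiden at 0.5 turned the sign of erythrocyte (0.62) for lesional against healthy, and of erythrocyte (1.12) for perilesional against healthy.

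Leaving out 1 library, the share difference for lesional against perilesional ran from -1.56 (without perilesional replicate 2) to 0.63 (without perilesional replicate 3) in pericyte, from -0.41 (without perilesional replicate 3) to 1.20 (without perilesional replicate 1) in vascular endothelial and from -0.90 (without perilesional replicate 3) to 2.07 (without perilesional replicate 2) in lymphatic endothelial. It also ran from -0.46 (without lesional replicate 1) to 0.67 (without lesional replicate 4) in macrophage or dendritic and from -0.65 (without perilesional replicate 2) to 1.11 (without perilesional replicate 3) in erythrocyte. The share difference for lesional against healthy ran from -1.80 (without lesional replicate 4) to 0.20 (without lesional replicate 3) in keratinocyte, from -5.10 (without healthy replicate 1) to 2.99 (without healthy replicate 2) in erythrocyte and from -0.30 (without healthy replicate 1) to 0.65 (without healthy replicate 2) in unnamed. The share difference for perilesional against healthy ran from -0.98 (without healthy replicate 2) to 0.45 (without healthy replicate 1) in fibroblast, from -1.12 (without perilesional replicate 3) to 1.07 (without perilesional replicate 2) in pericyte and from -1.54 (without perilesional replicate 3) to 0.54 (without perilesional replicate 2) in T. It also ran from -0.66 (without healthy replicate 2) to 0.33 (without healthy replicate 1) in melanocyte and from -5.09 (without healthy replicate 1) to 2.99 (without healthy replicate 2) in erythrocyte.

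For lesional against perilesional, the adjusted p with an estimated correlation and by fry was 0.181 and 0.315 for alarm, 0.0964 and 0.0954 for epidermal differentiation, 0.181 and 0.252 for proliferation and 0.0964 and 0.0945 for interferon gamma genes in keratinocyte cells, and 0.563 and 0.701 for matrix genes in fibroblast cells. The pair was 0.246 and 0.356 for matrix genes in pericyte cells, and 0.608 and 0.607 for interferon gamma genes in macrophage or dendritic cells, and 0.207 and 0.159 for interferon gamma genes in T cells. For lesional against healthy, the adjusted p with an estimated correlation and by fry was 0.0847 and 0.104 for alarm and 0.0847 and 0.0304 for interferon gamma genes in keratinocyte cells. The pair was 0.375 and 0.359 for inflammatory, 0.224 and 0.178 for matrix, 0.171 and 0.0577 for MHC class II, 0.375 and 0.359 for lymphoid chemokine and 0.439 and 0.431 for lymphoid organisation genes in fibroblast cells, and 0.0797 and 0.0646 for matrix and 0.0922 and 0.0646 for immediate early genes in pericyte cells. The pair was 0.124 and 0.0793 for resident macrophage, 0.124 and 0.0195 for mature dendritic, 0.169 and 0.196 for interferon gamma and 0.593 and 0.56 for inflammatory myeloid genes in macrophage or dendritic cells, and 0.475 and 0.0862 for interferon gamma and 0.475 and 0.311 for proliferation genes in T cells. The pair was 0.567 and 0.506 for NF-kB genes in vascular endothelial cells, and 0.473 and 0.50 for lymphoid chemokine genes in all cells. For perilesional against healthy, the adjusted p with an estimated correlation and by fry was 0.488 and 0.498 for alarm genes in keratinocyte cells, and 0.0902 and 0.0713 for MHC class II and 0.575 and 0.733 for inflammatory genes in fibroblast cells, and 0.357 and 0.28 for immediate early genes in pericyte cells. The pair was 0.276 and 0.208 for resident macrophage genes in macrophage or dendritic cells, and 0.91 and 0.796 for immediate early genes in vascular endothelial cells.

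For type I interferon genes in lesional against perilesional keratinocytes, the adjusted p with an estimated correlation was 0.229 with the replicate block and ran from 0.00361 (without perilesional replicate 1) to 0.0834 (without perilesional replicate 3). For lesional against healthy keratinocytes it ran from 0.0248 (without lesional replicate 1) to 0.0708 (without healthy replicate 1). For mature dendritic genes in perilesional against healthy skin it ran from 0.0263 (without perilesional replicate 1) to 0.127 (without perilesional replicate 3). The block, or pairing, changed no call but those given here. Depth limits the small classes, and the UMI floor left too few T and plasma cells for a count. Perilesional replicate 2 held under 20 T and under 20 plasma cells, so leaving it out gave no other value in those classes, and B cells gave none under any setting.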

Other observations

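Among the tests of explanations below, the test of fibroblast RNA was chosen before its result was seen, and the others were chosen after. Genes of T cell subsets held several values outside the comparisons above. Genes of Th17 cells had median log2 fold changes of 0.53 in lesional against perilesional and 0.70 in lesional against healthy T cells, where 3 were higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.635 and 0.609). Genes of T follicular helper and regulatory T cells had medians of 0.27 each in lesional against perilesional T cells (camera adjusted p = 0.635 and 0.443). Genes of endothelial activation and high endothelial venules, which admit lymphocytes, had a median of -0.17 in lesional against perilesional and -0.35 in lesional against healthy endothelium (camera adjusted p = 0.71 and 0.238). In the sum of all cells, 6 of 6 melanocyte markers were lower in lesional than in perilesional skin when adjusted over the list alone, with a median of -2.85 (adjusted p = 0.12 with an estimated correlation). An unnamed cluster led by SAA1, ACTA2 and MYLK held 1.13% ± 1.24 of lesional (n = 4), 0.449% ± 0.470 of perilesional (n = 3) and 2.88% ± 2.08 of healthy cells (n = 2). Erythrocytes were 1.03% ± 1.45 of healthy cells (n = 2), all of them in healthy replicate 2.

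Type I interferon genes rose as a set in lesional against perilesional keratinocytes. The 155 genes abundant in other classes and scarce in keratinocytes had a median of -0.016 (95% interval -0.31 to 0.17) against 1.60 (1.12 to 1.95) for the list. That argues against RNA rising alike from all other classes. The 155 genes pool classes whose shares rose and fell in lesional skin, so RNA from immune cells alone is not excluded. A difference between matrix formats as the whole cause is argued against, since the adjusted p with an estimated correlation was 0.0254 with the format as a term. Of all 35 splits the real one alone gave a p as small (0.000763, lowest of the others 0.0115), but the 8 splits that part the 3 pairs, of which 1, the real one, gave as small a p, are too few for a share under 0.05, the replicate block ended the call (adjusted p = 0.229 with an estimated correlation, median 1.56) and the list was picked from 231 list tests. A response of lesional keratinocytes to interferon is a candidate explanation. RNA from single other classes, the unequal make-up of the keratinocyte clusters and differences between donors stay open and untested.

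In pericytes and smooth muscle cells 12 genes fell in lesional against healthy skin, 4 of them from the 17 immediate early genes, whose list call was lost (adjusted p = 0.0922 with an estimated correlation). A handling response alike in all classes would lower them everywhere, but over 5 other classes the medians of the list centred on -0.40 (range -1.01 to 0.24) against -1.92 in pericytes. In perilesional against healthy skin, though, the median was -1.63 in vascular endothelium and -1.45 in pericytes. A difference between formats is argued against as well, since 12 of the 12 genes that fell, the 4 included, were past 0.05 in the newer format alone. A handling response of vessel cells, the unequal make-up of the pericyte clusters and a lower activity of these genes in diseased skin stay open, and the data may hold any of them.

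For the 8 genes that fell in lesional against healthy macrophages and dendritic cells, lymphatic endothelial cells, which also express LYVE1, would bring their chemokine CCL21, but its 6 UMIs in healthy cells of this class were 0.0511% of the 11744 that the 445 LYVE1 UMIs would need. RNA from fibroblasts, scaled to their gene DCN, gave 0.454% of the UMIs of the median of the 8 genes (range 0.00168% to 7.04%), and fibroblast markers had a median log2 fold change of -0.31 (95% interval -2.56 to 0.80). Of the 8, 2 were abundant in another class and scarce here, and 6 passed with such genes left out. Cells of low UMI count missing from the older-format libraries are argued against as the whole cause, since 8 of the 8 genes were past 0.05 in the newer format alone, where each library had the same minimum. With the common UMI floor, 0 of the 8 passed with 57 and 26 healthy cells left. A loss of resident macrophages, seen as the smaller share of the C1QA and RNASE1 cluster in the newer-format libraries, is a candidate explanation. RNA from other classes and donor differences stay open and untested.

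For lesional against perilesional skin, edgeR called 0 genes in the real split. Each of the 35 splits must give at least that, so the comparison says nothing about chance. The highest counts of the other splits were 780 in all cells, 1085 in keratinocytes, 559 in fibroblasts, 911 in pericytes, 1253 in vascular endothelial cells and 373 in macrophages or dendritic cells, each from the split of older against newer format. The real split parts each of the 3 pairs, and of the 8 splits that do so none called a gene in any of these classes. The split by format keeps each pair whole, so format, pair and donor cannot be told apart as the source of its calls, and its counts are not comparable with those of the lesion. Within the newer format alone edgeR called 0 genes in all cells, keratinocytes, fibroblasts and vascular endothelial cells and 1 each in pericytes and in macrophages or dendritic cells, and with the replicate block 11, 1 and 14 genes in keratinocytes, fibroblasts and pericytes. Between sites, 5 of 99 splits gave at least the 1 gene of all cells (highest other 703), so chance cannot be excluded for it. The 0 of keratinocytes (100 splits, highest other 937) and the 0 of fibroblasts (99 splits, highest other 584) say nothing about chance, and each highest count again came from the split by format.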
